A study of Homo sapiens with 6 samples.

How the data were processed

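RNA sequencing measured gene expression in 6 libraries labelled as Hep3B, a line derived from a human hepatocellular carcinoma. In the labels 3 libraries carry a control short hairpin RNA (shRNA) and 3 carry an shRNA against HYOU1. Per the labels' protocols, RNA integrity was checked, polyadenylated RNA was captured with oligo(dT) beads, and cDNA was primed with random hexamers after fragmentation. The protocols name no step that marks the strand, and whether strand was used in counting is not given in the sources used here. Values of genes that overlap on opposite strands are therefore uncertain. The labels do not say whether the 3 replicates of a group were separate cultures. The p-values then measure the spread between these libraries, which may be technical.

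The authors deposited 1 table of FPKM values (fragment counts divided by gene length in kilobases and by the scaled library total) for 58735 genes, with the gene length, coordinates and biotype of each gene. The aligner, the counting tool and their versions are not given in the sources used here. All 58735 gene identifiers and coordinates of the deposited table matched GENCODE release 29 (Ensembl 94) on GRCh38. The names of 27 genes differed from that annotation, and some of these had been turned into dates. The product of FPKM and gene length came in whole multiples of a single step in each library, for 99.9% to 100.0% of values within a tolerance of 0.01 fragments. From these steps, 16893091, 18210661 and 17759595 fragments were recovered for control replicates 1, 2 and 3. The HYOU1 shRNA replicates 1, 2 and 3 held 17537179, 18233240 and 17603796. The totals by which the deposited FPKM had been scaled equalled median-of-ratios size factors recomputed from the recovered fragments, so the values already held a correction between libraries. A count of 3 fragments was worth between 0.160 and 0.176 FPKM for a gene of 1 kb. Such floors cover counting error only.

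Values were used as deposited and transformed to log2(FPKM + 0.1). Genes with a mean of at least 1 FPKM over the 6 libraries were tested, which left 12448. The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend and robust priors). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene in the text comes from this test unless another is named. Fold changes are on the log2(FPKM + 0.1) scale, which understates changes of weakly expressed genes. Gene lists were tested on the same values with camera at a preset correlation of 0.01, for lists with at least 5 tested members. There were 23 lists of pathways and cell functions, of which 22 could be tested. A further 9 lists covered RNA quality, other cell types and control genes, of which 6 could be tested as a family of their own. camera was repeated with an estimated correlation. fry was run for the direction of each list as a whole, and its results are not given here. Chromosomes were tested with camera and an estimated correlation.

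The test, the gene lists and the rule for named genes were fixed before the data were examined. The rule names HYOU1, HSPA5, HSP90B1, DNAJC3, DDIT3, ATF4, XBP1 and SIL1 whatever their result. It adds the 10 largest rises and 10 largest falls among called protein-coding genes without overlap between the groups and with a mean of at least 5 FPKM in the higher group. Up to 3 non-coding genes were taken under the same limits. Up to 4 called members with the largest change stand as examples of each list, or the 2 members with the highest mean where none was called. Other genes are said to have been chosen after their values were seen. The results for a few genes, 1 gene list and 1 test on the identity of the cells are not reported here.

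Alternatives fixed beforehand were pseudocounts of 1 and 0.01, filters of 0.1, 5 and none, median-of-ratios, quantile and TPM scaling, the replicate number as a block, no variance trend, protein-coding genes alone, and leaving out each library in turn. A GC correction, alone, without control replicate 1 and with the block, and voom on the recovered fragments were chosen after seeing the data. The GC correction removed, in each library, a lowess trend (span 0.3) of the deviation from the gene mean on the GC content of the longest transcript. The 6 tested genes without a GC value were left as they were. The correction also removes any real difference between the groups that follows GC content. A test on counts was planned only for a table of counts and was not run.

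The fits were tested on simulated data for the 12448 genes, with 200 genes changed in each of 10 simulations and the spread taken from the libraries other than control replicate 1. This simulation replaced a first version with 1 run and a fixed spread, after the results of that version had been seen. Without a GC trend the test found 77.9% of genes changed 1.5-fold, 93.4% of those changed 2-fold and 99.5% of those changed 4-fold, and 5.35% of its calls were false. With the GC trend of control replicate 1 added to that library it found 0.746%, 34.8% and 92.0%, and 1.40% of calls were false. After the GC correction it found 76.4%, 93.6% and 99.5%, and 6.02% of calls were false. With control replicate 1 left out it found 67.3%, 89.3% and 98.6%, and 8.31% of calls were false. The simulated control replicate 1 carried the GC trend but no other deviation of that library. In the data it still stood apart after the GC correction, with SDs of its log2 differences from the other controls of 0.586 and 0.622. Between those controls the SD was 0.441. The simulated shares after the correction therefore describe a cleaner library than the real one. A planted list of 25 genes shifted by 0.5 on the log2 scale was called by camera in all 10 simulations with and without the GC trend, and 0 of 210 unchanged lists were called in either. These lists held random genes, simulated independently of each other apart from the GC trend. They could not show false calls of lists whose members vary together or share their GC content.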

Results

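The series compared the transcriptome of cells carrying an shRNA against HYOU1 with that of cells carrying a control shRNA. HYOU1 encodes a large chaperone of the endoplasmic reticulum (ER). The labels name Hep3B, a hepatocellular carcinoma line, for all 6 libraries. Each group held 3 libraries, with 16893091 to 18233240 fragments per library as recovered from the deposited FPKM. Of 58735 genes in the table, 30059 were above 0 in at least 1 library and 12448 were tested.

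HYOU1 (ENSG00000149428, chromosome 11, 119044189 to 119057202 on GRCh38) was at 37.6, 58.2 and 59.5 FPKM in control replicates 1, 2 and 3, and at 2.35, 2.32 and 2.37 FPKM in HYOU1 shRNA replicates 1, 2 and 3. The means were 51.8 ± 12.3 and 2.35 ± 0.0250 FPKM (SD, n = 3 each). The log2 fold change was -4.38 with a standard error of 0.20 (limma, adjusted p = 0.00119), a 20.8-fold lower level. The level of HYOU1 in each of the 6 libraries matched its label.

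The libraries labelled Hep3B held few transcripts of secreted hepatocyte proteins in either group. Of 36 such genes, 4 reached a mean of 1 FPKM, namely C3, RBP4, VTN and F10, and 7 were listed at 0 in every library. ALB, which encodes albumin, was listed at 0 in every library, where 3 fragments would have been worth at most 0.0520 FPKM. AFP had 3 fragments in all libraries together. No housekeeping gene of 14 was listed at 0. Of 35 hepatocyte transcription factors and metabolic enzymes, 8 reached a mean of 1 FPKM. Of the markers of other cell types, 8 of 10 biliary and 5 of 12 fibroblast and stellate cell genes reached it, and none of the 15 immune or 10 endothelial genes did.

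Control replicate 1 stood apart from the other libraries. Its log2 values correlated across genes with those of control replicates 2 and 3 at Pearson's r of 0.906 and 0.892, against 0.971 between these 2 replicates. Genes are not independent replicates, and these values describe the libraries only. Relative to the mean of control replicates 2 and 3 it was higher by a median of 0.76 on the log2 scale in the 10% of genes with the lowest GC content and lower, at -1.0, in the 10% with the highest. Fragments of mitochondrial genes made up 7.59%, 5.17% and 4.96% of control replicates 1, 2 and 3 and 3.39%, 3.84% and 3.52% of HYOU1 shRNA replicates 1, 2 and 3. Counts are also given without control replicate 1 and after the GC correction.

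**Figure D1:**
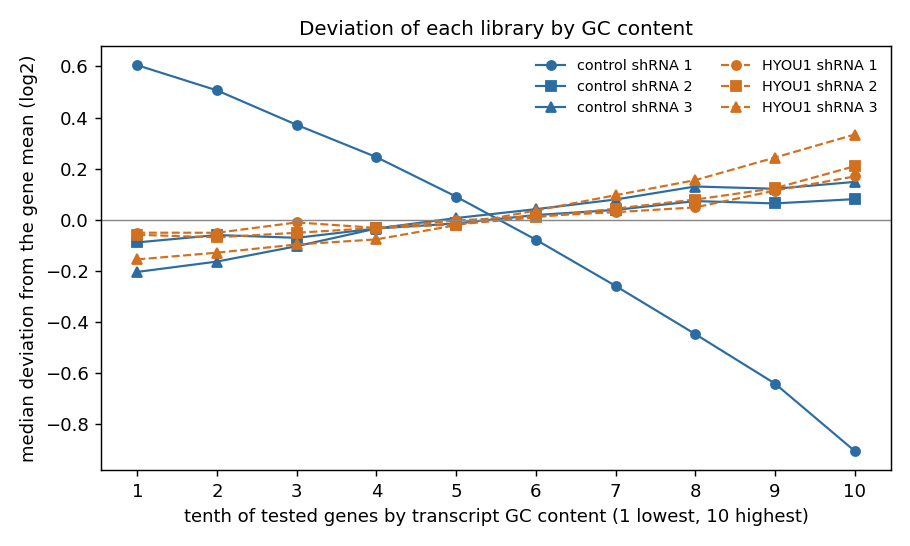
Median deviation of each library from the gene mean (log2, vertical axis) in 10 equal parts of the 12448 tested genes ordered by transcript GC content (horizontal axis), with solid blue lines for the 3 control libraries and dashed orange lines for the 3 HYOU1 shRNA libraries. Control replicate 1 falls from 0.60 in the part with the lowest GC content to -0.91 in the highest, and the other 5 libraries lie between -0.20 and 0.33.

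With HYOU1 shRNA, 1526 genes changed, of which 822 rose and 704 fell (limma, adjusted p under 0.05). At least 2-fold changes were seen in 638 genes, with 378 higher and 260 lower. In 5528 genes, 44.4% of those tested, the values of the groups did not overlap, where chance gives 10%. Without control replicate 1, 5518 genes changed (3062 rose, 2456 fell), and after the GC correction 5047 did (2534 rose, 2513 fell). Of the 1526 genes, 1523 stayed past the threshold in the same direction without control replicate 1 and 1468 after the GC correction. The count fell to 357 without control replicate 2, to 1022 without control replicate 3, and to 126, 85 and 49 without HYOU1 shRNA replicates 1, 2 and 3. Without control replicate 3, 428 genes fell. The 2-fold count was 302 without control replicate 2, and 125, 85 and 49 without HYOU1 shRNA replicates 1, 2 and 3.

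The genes with the largest rises included COL6A2, a collagen VI chain, KLF2, a zinc finger transcription factor, and AREG, an EGF receptor ligand. COL6A2 rose from 0.913 ± 0.314 to 9.79 ± 0.344 FPKM (SD, n = 3 each), a log2 fold change of 3.34 with a standard error of 0.25 (limma, adjusted p = 0.00289). KLF2 rose by 3.24, ARC by 2.99, TEX19 by 2.90 and XAGE2 by 2.80. INHBB, the beta-B subunit of inhibin and activin, rose by 2.74, and KCNS3, a potassium channel subunit, by 2.60. AREG rose by 2.44 and GRB7, an adaptor of receptor tyrosine kinases, by 2.12. HBA2 rose by 2.81 (limma, adjusted p = 0.0499), was at 2.34 FPKM in control replicate 1, and was not past the threshold after the GC correction (adjusted p = 0.108). Its reads may be shared with the near-identical HBA1, so its value is uncertain. ARC, TEX19 and XAGE2 were not past the threshold without HYOU1 shRNA replicate 1, 2 or 3 (adjusted p between 0.0758 and 0.0864). KLF2 was not past it without HYOU1 shRNA replicates 2 and 3 (adjusted p = 0.0525 and 0.0550). HBA2 passed only when the library left out was control replicate 1.

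The largest fall after HYOU1 itself was that of MAP2K6, a kinase upstream of p38, from 8.65 ± 1.88 to 0.681 ± 0.0693 FPKM (SD, n = 3 each). Its log2 fold change was -3.47 with a standard error of 0.19 (limma, adjusted p = 0.00168). STS, steroid sulfatase, fell by 2.63, and PDK4, a kinase that inhibits pyruvate dehydrogenase, by 2.46. DSEL fell by 2.34, ARSB, a lysosomal sulfatase, by 2.33, and PSAT1, an enzyme of serine synthesis, by 2.30. DKK1, a secreted WNT antagonist, fell by 2.23 and C4BPA, a regulator of complement, by 2.17. CTDNEP1 fell by 2.13 and overlaps ELP5 on the other strand, which was at 18.4 ± 2.12 and 20.5 ± 0.689 FPKM (SD, n = 3 each). DSEL and CTDNEP1 were not past the threshold without HYOU1 shRNA replicate 3 (adjusted p = 0.0522 and 0.0515). Among non-coding genes, AC004585.1 rose by 3.64 and MIR589 by 3.48, and MIR4767 fell by 2.61. MIR589 lies inside FBXL18, and MIR4767 inside PUDP on the other strand, so their reads may belong to these genes. AC004585.1 and MIR4767 were not past the threshold without HYOU1 shRNA replicate 1, 2 or 3 (adjusted p between 0.0628 and 0.0864), nor was MIR4767 without control replicate 2 (adjusted p = 0.060).

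**Figure D2:**
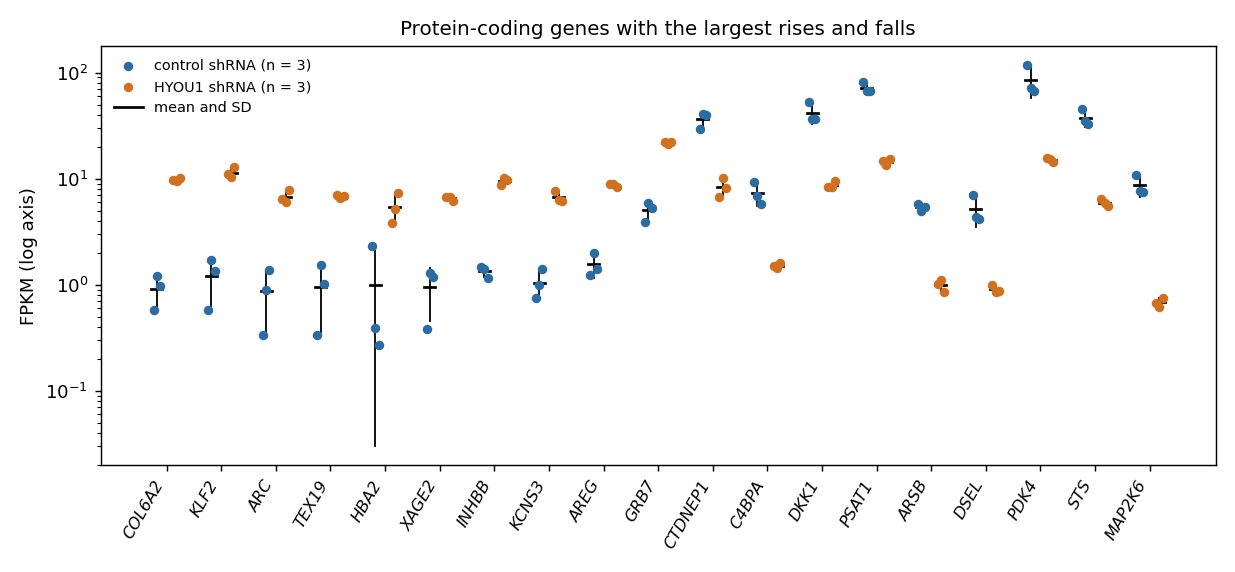
FPKM (vertical log axis) in each library for the protein-coding genes with the largest rises (left) and falls (right), HYOU1 left out, with blue points for control shRNA, orange points for HYOU1 shRNA, and black bars for the mean and SD of 3 libraries. COL6A2 lies near 9.79 FPKM with HYOU1 shRNA against 0.913 in controls, and MAP2K6 near 0.681 against 8.65. The lower SD bar of HBA2, which would pass below 0, is truncated.

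ER chaperones and folding enzymes fell as a group. Of 26 tested members, 8 fell, 1 rose and 17 did not pass (camera, adjusted p = 0.000434, and adjusted p = 0.137 with an estimated correlation). DNAJC3, a co-chaperone that inhibits the kinase PERK, fell by 1.38. HSPA5, the main ER chaperone BiP, fell from 447 ± 39.5 to 189 ± 1.72 FPKM (SD, n = 3 each), a log2 fold change of -1.24 (limma, adjusted p = 0.00324). DNAJB11, a co-chaperone of BiP, fell by 0.97 and UGGT1, a sensor of glycoprotein folding, by 0.88. The member that rose was PDIA5, by 0.86, named after its value was seen. HSP90B1, the ER form of HSP90, differed by -0.52 and did not pass (adjusted p = 0.143), but did after the GC correction, at -0.38 (adjusted p = 0.00587), and without control replicate 1, at -0.29 (adjusted p = 0.00866). SIL1, a nucleotide exchange factor of BiP, differed by -0.17 (adjusted p = 0.706), by -0.42 after the GC correction (adjusted p = 0.0337), by -0.52 without control replicate 1 (adjusted p = 0.00134) and by 0.036 without control replicate 3. DNAJC3 was not past the threshold without HYOU1 shRNA replicates 1, 2 or 3 (adjusted p = 0.106, 0.104 and 0.108) or control replicate 2 (0.0634), or without a filter (adjusted p = 0.0529). With p adjusted over the list alone, 15 members fell and 1 rose. Leaving out control replicate 1, 20 fell and 5 rose, and after the GC correction 18 fell and 5 rose.

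The list of the PERK-ATF4 integrated stress response was lower as well. Of 31 tested members 8 fell, 2 rose and 21 did not pass (camera, adjusted p = 0.0307, and adjusted p = 0.310 with an estimated correlation). Besides PSAT1, SLC7A11, the cystine transporter, fell by 1.90, CTH, which makes cysteine, by 1.13, and SLC7A5, a transporter of large neutral amino acids, by 0.97. MTHFD2 and ATF3, named after their values were seen, rose by 0.87 and 0.62. ATF4 itself differed by -0.24 (adjusted p = 0.221), and passed after the GC correction, at -0.43 (adjusted p = 0.00654), and without control replicate 1, at -0.34 (adjusted p = 0.00288). DDIT3, which encodes CHOP, differed by 0.21 (adjusted p = 0.514). XBP1, a transcription factor of the unfolded protein response, differed by 0.16 (adjusted p = 0.347) and passed without control replicate 1, at 0.20 (adjusted p = 0.0405). The list was not called without control replicate 2 or 3 or HYOU1 shRNA replicate 1 (adjusted p = 0.0726, 0.106 and 0.0579), nor with a filter of 0.1 or 5 FPKM (adjusted p = 0.0652 and 0.0583). With the replicate number as a block camera did not call it either (adjusted p = 0.0501). There were 11 falls and 3 rises when adjusted over the list alone. In the fit without control replicate 1, 15 fell and 5 rose, and after the GC correction 14 fell and 4 rose.

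**Figure D3:**
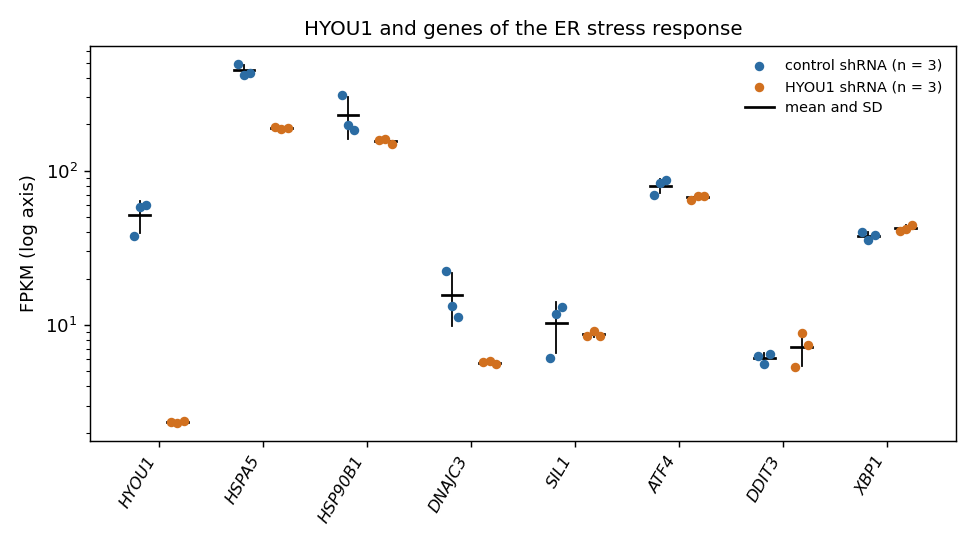
FPKM (vertical log axis) of HYOU1 and the 7 genes of the ER stress response that were fixed beforehand, with blue points for the 3 control libraries, orange points for the 3 HYOU1 shRNA libraries, and black bars for the mean and SD. HYOU1 lies at 2.32 to 2.37 FPKM with HYOU1 shRNA against 37.6 to 59.5 in controls. Of the 8 genes drawn, the values of the groups overlap for SIL1 and DDIT3 and are separated for the others.

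Genes of ER-associated degradation and translocation were not called as a list. Of 30 tested members 4 fell, 1 rose and 25 did not pass (camera, adjusted p = 0.124). SSR1, a subunit of the translocon-associated complex, fell by 1.07, SEL1L, of the HRD1 ubiquitin ligase, by 0.91, SEC61B, of the translocation channel, by 0.77 and DERL2 by 0.72. The gene that rose was SEC24D, by 0.72, named after its value was seen. When adjusted over the list alone, 7 fell and 2 rose. Without control replicate 1, 10 fell and 7 rose.

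Genes of the cytosolic heat shock response rose. Of 17 tested members 5 rose, 0 fell and 12 did not pass (camera, adjusted p = 0.00680, and adjusted p = 0.186 with an estimated correlation). HSPA1B rose by 1.33 and HSPA1A by 1.25. These are near-identical copies of the inducible HSP70 gene, and the split of reads between them is uncertain. DNAJB1, a co-chaperone of HSP70, rose by 0.75 and BAG3 by 0.63. A total of 6 rose when adjusted over the list alone, and in the fit without control replicate 1 14 rose and 0 fell. After the GC correction 11 rose and 0 fell.

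Early response genes of MAPK and growth factor signalling made up the list with the lowest adjusted p among the 22 tested lists of pathways and cell functions. Of 24 tested members 13 rose, 0 fell and 11 did not pass (camera, adjusted p = 6.73e-05, and adjusted p = 0.295 with an estimated correlation). Besides AREG, DUSP6, a phosphatase of ERK, rose by 1.79, FOSL1, an AP-1 subunit, by 1.77 and SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, by 1.69. Of these genes 14 rose and 2 fell when adjusted over the list alone. Without control replicate 1, 17 rose and 3 fell, and after the GC correction 18 rose and 3 fell.

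Interferon-stimulated genes and genes of NF-kB and acute-phase inflammation were also higher. Of 23 interferon-stimulated genes 7 rose, 0 fell and 16 did not pass (camera, adjusted p = 0.00374, and adjusted p = 0.137 with an estimated correlation). OASL rose by 2.03, ISG15, a ubiquitin-like modifier, by 1.90, DDX58, which encodes the RNA sensor RIG-I, by 1.86, and IFI44 by 1.32. Of 13 NF-kB genes 6 rose, 0 fell and 7 did not pass (camera, adjusted p = 0.00407, and adjusted p = 0.186 with an estimated correlation). RELB and NFKB2, subunits of the non-canonical NF-kB dimer, rose by 1.72 and 1.52, CXCL8, a neutrophil chemokine, by 1.15 and SOD2 by 1.04. The NF-kB list was not called with a filter of 0.1 FPKM or without a filter (adjusted p = 0.281 and 0.557), which add weakly expressed members, and the interferon list was not called with a filter of 5 FPKM (adjusted p = 0.146). Adjusted over the list alone, 11 interferon-stimulated genes rose and 1 fell, and 7 NF-kB genes rose. Without control replicate 1, 13 rose and 2 fell, and 8 rose and 1 fell, respectively.

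Genes of cholesterol synthesis and uptake were higher as a list, and those of fatty acid oxidation and ketogenesis were lower as a list. Of 24 cholesterol genes 6 rose, 0 fell and 18 did not pass (camera, adjusted p = 0.00104, and adjusted p = 0.137 with an estimated correlation). HMGCS1, which makes HMG-CoA, rose by 1.05 and FDFT1, squalene synthase, by 0.91. Of 20 genes of fatty acid oxidation and ketogenesis 4 fell, 0 rose and 16 did not pass (camera, adjusted p = 0.00835, and adjusted p = 0.140 with an estimated correlation). Besides PDK4, PPARA, a transcription factor of fatty acid oxidation, fell by 1.22, SLC25A20, the mitochondrial carnitine carrier, by 0.97 and ETFDH by 0.93. For cholesterol 8 genes rose, and for oxidation 7 fell, when adjusted over the list alone. Leaving out control replicate 1, 12 cholesterol genes rose and 1 fell, and 8 oxidation genes fell and 2 rose. The 2 oxidation genes that rose, CPT1A at 0.26 and ECI1 at 0.32, also passed after the GC correction. They are named after their values were seen.

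In the NRF2 antioxidant list, of 27 tested members 5 fell, 0 rose and 22 did not pass (camera, adjusted p = 0.00163, and adjusted p = 0.137 with an estimated correlation). AKR1C1 fell by 1.93, AKR1C2 by 1.80 and AKR1C3 by 0.90. These aldo-keto reductases, which reduce steroids and other carbonyl compounds, are near-identical copies whose reads may be shared. SLC7A11, which also stands in the PERK-ATF4 list, fell by 1.90. Falls numbered 6 when adjusted over the list alone, and in the fit without control replicate 1 15 fell and 1 rose. After the GC correction 16 fell and 0 rose.

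Regulators of apoptosis rose in 7 of 24 tested members, with 0 falling and 17 not passing (camera, adjusted p = 0.0289, and adjusted p = 0.181 with an estimated correlation). BBC3, BIK and BMF, which encode BH3-only proteins, rose by 2.00, 1.32 and 0.91, and BAK1, an effector of mitochondrial permeabilisation, by 0.92. BCL2L1 and MCL1, which encode inhibitors of apoptosis in their main forms, rose by 0.66 and 0.63 and are named after their values were seen. The list was not called without control replicate 2 or 3 (adjusted p = 0.0807 and 0.0612). Mitosis and G2/M genes rose in 4 of 34, with 0 falling and 30 not passing (camera, adjusted p = 0.0363, and adjusted p = 0.453 with an estimated correlation). Among all tested genes, 1526 of 12448 were called. AURKB rose by 1.07, UBE2C by 0.85, KIF2C by 0.65 and CDC20 by 0.63. The mitosis list was not called without control replicates 2 or 3 (adjusted p = 0.153 and 0.257) or HYOU1 shRNA replicates 1 or 2 (adjusted p = 0.0596 and 0.0644). Nor was it called with a filter of 5 FPKM, quantile normalization, protein-coding genes alone or the replicate block (adjusted p = 0.0583, 0.138, 0.0509 and 0.0750). Adjusted over the list alone, 7 regulators of apoptosis rose, and 8 mitosis genes rose and 1 fell. Leaving out control replicate 1, 13 regulators of apoptosis rose and 1 fell, and 21 mitosis genes rose and 3 fell. Those 3 mitosis genes were MKI67, FOXM1 and CENPF, at -0.45, -0.34 and -0.21 in that fit, named after their values were seen.

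**Figure D4:**
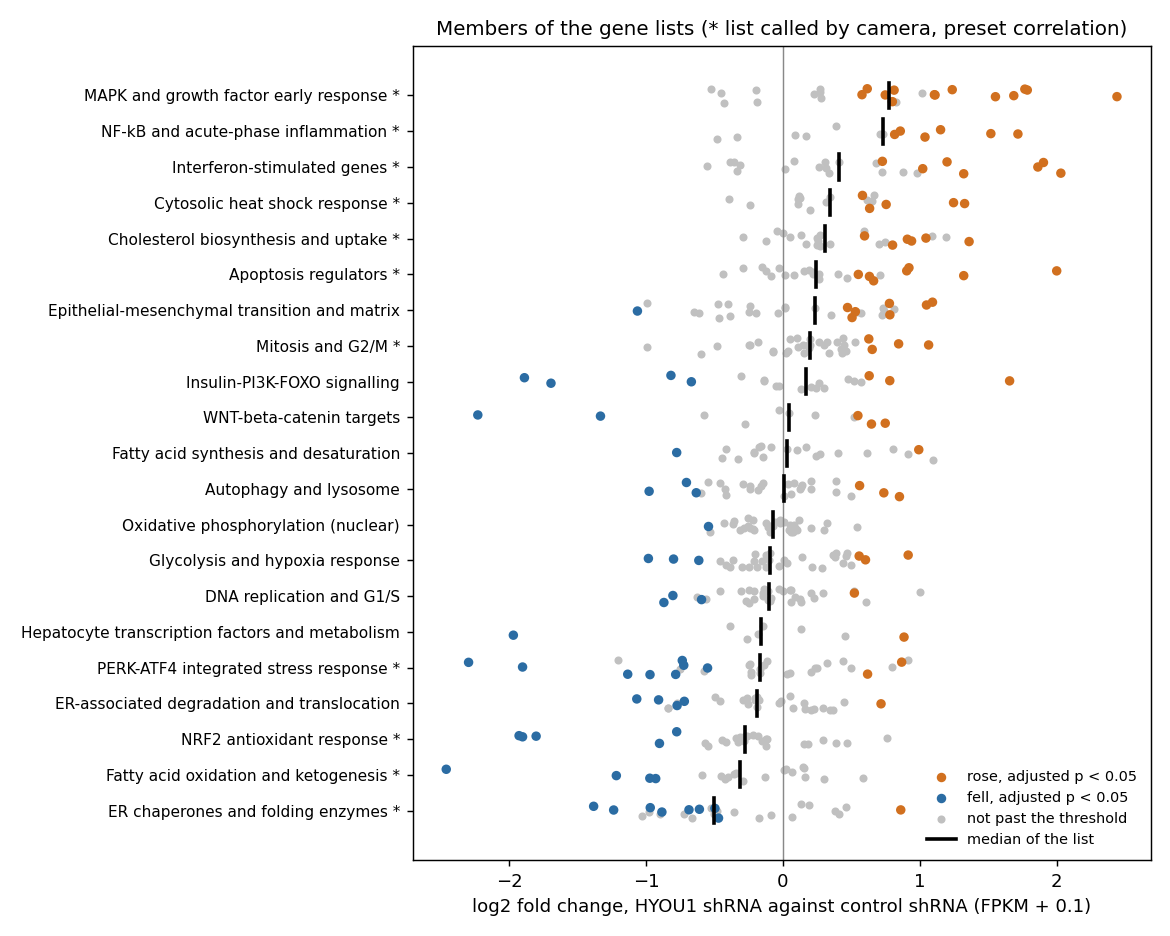
Log2 fold change of each tested member (horizontal axis) of 21 of the 22 tested gene lists (rows, ordered by median), with orange points for called rises, blue points for called falls, grey points for members not past the threshold and black bars for list medians. Stars mark the 11 lists called by camera at the preset correlation, of which none was called with an estimated correlation.

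The other lists reported here were not called, and each adjusted p of a list in this paragraph is that of camera. Among 29 genes of epithelial-mesenchymal transition and matrix 7 rose and 1 fell (camera, adjusted p = 0.247), with COL1A1 at 1.09, TGFBI at 1.05 and ITGAV at -1.06. Of 20 insulin, PI3K and FOXO genes 3 rose and 4 fell (adjusted p = 0.736), with IGFBP1 at -1.89, SESN3 at -1.69 and TXNIP at 1.66. Of 11 WNT targets 3 rose and 2 fell (adjusted p = 0.804), with DKK1 and AXIN2 at -2.23 and -1.33 and MYC and CCND1 at 0.75 and 0.65. In 8 hepatocyte transcription factors and metabolic enzymes (camera, adjusted p = 0.572) CPS1, of the urea cycle, fell by 1.97 and CYP3A5 rose by 0.89. Among 34 genes of DNA replication and G1/S 1 rose and 3 fell (adjusted p = 0.279), with GINS2 at -0.80 and MCM6 at 0.52. Of 33 genes of glycolysis and hypoxia 3 rose and 3 fell (adjusted p = 0.710), with ADM at -0.98 and ENO2 at 0.92. Of 29 autophagy and lysosome genes 3 rose and 3 fell (adjusted p = 0.553), with ATP6V0D1 at -0.98 and NPC1 at 0.85. Of 21 genes of fatty acid synthesis 1 rose and 1 fell (adjusted p = 0.733), DGAT2 at 0.99 and ME1 at -0.78. Of 35 nuclear genes of oxidative phosphorylation (camera, adjusted p = 0.130) 1 fell, UQCRQ at -0.54. Without control replicate 1 the list was called lower (camera, adjusted p = 0.0140). The median and the mean differed in sign for WNT targets (0.045 and -0.15) and for autophagy genes (0.0050 and -0.054), and the test gave the sign of the mean. When adjusted over the list alone, 12 matrix genes rose and 5 fell, 3 insulin genes rose and 5 fell, 3 WNT targets rose and 3 fell, and 1 hepatocyte factor or enzyme gene rose and 1 fell. By the same adjustment 2 replication genes rose and 3 fell, 5 glycolysis genes rose and 4 fell, 3 autophagy genes rose and 4 fell, 2 fatty acid synthesis genes rose and 1 fell, and 0 oxidative phosphorylation genes changed. Leaving out control replicate 1, 14 matrix genes rose and 8 fell, 9 insulin genes rose and 6 fell, 4 WNT targets rose and 3 fell, and 1 hepatocyte factor or enzyme gene rose and 4 fell. In that fit 5 replication genes rose and 10 fell, 8 glycolysis genes rose and 11 fell, 7 autophagy genes rose and 10 fell, 5 fatty acid synthesis genes rose and 2 fell, and 9 oxidative phosphorylation genes fell. None of the 4 tested genes for secreted hepatocyte proteins was called, and the list was too short for the test, with C3 at 64.8 ± 9.67 and 51.0 ± 2.47 FPKM (SD, n = 3 each). Of these 4, C3 and RBP4 were called lower without control replicate 1, at -0.46 and -0.72 (adjusted p = 0.000699 and 0.00169), and after the GC correction (adjusted p = 0.000982 and 0.00121).

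Among the lists for RNA quality and other cells, mitochondrially encoded mRNAs fell in 8 of 13 members with 0 rising (camera, adjusted p = 5.19e-07, and adjusted p = 0.537 with an estimated correlation). MT-CYB fell by 1.4, MT-ND3 by 1.01, MT-ND5 by 0.94 and MT-CO3 by 0.89. Without control replicate 1 all 13 fell. Cytosolic ribosomal protein genes rose in 3 of 40 with 0 falling (camera, adjusted p = 0.000167, and adjusted p = 0.537 with an estimated correlation), namely RPL12, RPS12 and RPS19 by 0.63, 0.45 and 0.39. RPS19 did not pass after the GC correction (adjusted p = 0.253). In the fit without control replicate 1, 20 of the 40 rose and 0 fell, and after the GC correction 11 rose and 0 fell. Of 14 housekeeping genes TFRC, the transferrin receptor, fell by 1.71 and the others did not pass. Leaving out control replicate 1, B2M and YWHAZ also rose, by 0.38 and 0.31, and GUSB was lower at -0.38, and these 3 passed after the GC correction as well. Of 5 tested fibroblast and stellate cell markers (camera, adjusted p = 0.968) DES rose by 2.00, COL1A1 by 1.09, and DCN fell by 1.35. The median of the 5 was -0.16 and their mean 0.19. Of 8 tested biliary markers 1 fell and 0 rose (camera, adjusted p = 0.499), and without control replicate 1 2 fell and 3 rose. Of 7 tested replication-dependent histone genes and 2 nuclear-retained long RNAs limma called 0, where 3926 genes overall had an unadjusted p under 0.05. Among the histone genes 1 rose and 3 fell without control replicate 1, and 0 rose and 3 fell after the GC correction. NEAT1 was called at -0.56 and MALAT1 at 0.34 without control replicate 1 (adjusted p = 0.00101 and 0.00330), where MALAT1 differed by -0.25 with all libraries, and neither passed after the GC correction. No chromosome was called against the other genes (camera with an estimated correlation, lowest adjusted p = 0.771). The 35 tested mitochondrial genes, with a median of -0.89, were not called by this test either. It therefore cannot show that no chromosome differed.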

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

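The GC correction, its combinations, voom and array weights were chosen after seeing the data, and the other settings before. HYOU1 stayed lower and past the threshold in every setting tried, between -4.59 and -4.26 with 1 library left out. The counts of changed, rising, falling and 2-fold changed genes stayed within 1.5 times the reported ones with a pseudocount of 0.01, a filter of 0.1 FPKM, median-of-ratios, quantile or TPM scaling, no variance trend, protein-coding genes alone, and voom on the recovered fragments. With an estimated correlation, camera called 0 lists higher and 0 lower, against 7 and 4. At a pseudocount of 1, 404 genes changed at least 2-fold. Without a filter 770 genes changed (433 rose, 337 fell), and 627 of the 1526 genes were among them. With a filter of 5 FPKM, which left 7178 genes to test, 938 changed (525 rose, 413 fell), 279 of them at least 2-fold. After the GC correction 5047 changed (2534 rose, 2513 fell), and with control replicate 1 also left out 6051 did (3112 rose, 2939 fell). With 1 library left out, 49 to 5518 genes changed, 22 to 3062 rose, 27 to 2456 fell, 49 to 682 changed at least 2-fold, and 5 to 7 lists were called higher and 3 to 5 lower. The changed genes numbered 5518, 357 and 1022 without control replicates 1, 2 and 3, and 126, 85 and 49 without HYOU1 shRNA replicates 1, 2 and 3. SIL1, which was not called, lay at -0.52 and was called without control replicate 1, and at 0.036 without control replicate 3. Beyond the smaller numbers of genes or libraries in some settings, the cause was not tested. Of 392 comparisons of other named genes in settings with all libraries, 375 kept their direction and side of the threshold, 10 lost the call and 7 gained it. HBA2 lost it in 9 of 13 settings with all libraries. With 1 library left out, 140 of 174 kept it, 29 lost the call, 4 gained it and SIL1 changed sign. With the GC correction and control replicate 1 left out, 26 of 29 kept it and 3 gained the call. For the 11 called lists, 144 of 154 comparisons with all libraries kept the call and 10 lost it, 57 of 66 with 1 library left out kept it and 9 lost it, and with the GC correction and control replicate 1 left out all 11 kept it. limma's array weights did not converge and were not used. A test on counts, planned for a table of counts, was not run. Genes near the worth of 3 fragments, 0.160 to 0.176 FPKM for a gene of 1 kb, were not resolved at this depth.

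Whether equal replicate numbers mark shared cultures or days is not given in the labels. Deviations of same-numbered libraries from their group means correlated across genes at 0.125, -0.093 and 0.170 for replicates 1, 2 and 3. After the GC correction these were 0.019, -0.080 and 0.060. Control replicates 1 and 3 correlated best with the HYOU1 shRNA replicate of their own number, and control replicate 2 with HYOU1 shRNA replicate 3. These values do not decide whether the samples are paired. With the replicate block 940 genes changed (525 rose, 415 fell) and camera called 6 lists higher and 3 lower, without the mitosis and PERK-ATF4 lists, and with the GC correction as well 4505 did (2283 rose, 2222 fell).

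Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many changed, rising, falling or 2-fold changed genes (1526, 822, 704 and 638) or lists called in one direction (7 higher, 4 lower). In the other splits limma called at most 0 genes, with 64 to 641 at an unadjusted p under 0.05 against 3926 in the real one, and camera called at most 3 lists in one direction. These 10 splits are too few for a share under 0.05.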

Other observations

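The first test of the squamous markers and the tests of the genes around ALB and of depth in control replicate 1 were chosen before their results were seen, and the other tests in this part after. Families of protein-coding genes that share the letters of their symbol were tested with camera. Of 337 families with at least 5 tested members 0 were called, with 33 at an unadjusted p under 0.05, and the lowest adjusted p was 0.050 (0.988 with an estimated correlation). The genes named here were therefore picked one by one after their values were seen, from the 12 families with the lowest p. Of 12 KLF transcription factors 3 rose, KLF2, KLF6 by 1.72 and KLF4 by 0.67. Of 16 DUSP phosphatases 6 rose, led by DUSP9 at 1.94, and DUSP16 fell by 1.09. Of 15 PDE genes, which include the cyclic nucleotide phosphodiesterases, 5 fell, led by PDE7B at -1.98 and PDE3B at -1.52. Of 11 ALG genes, which act in N-glycan precursor synthesis in the ER, 3 fell, ALG9 by 1.49, ALG8 by 0.88 and ALG6 by 0.77.

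Control replicate 1 differed from control replicates 2 and 3 along the GC content of genes, with a Spearman correlation of -0.81 across genes, which is consistent with a GC bias in that library. Lower depth was argued against, since among the 25% of genes with the highest expression the SD of its difference from replicate 2 was 4.90 times that between replicates 2 and 3. After the GC correction its correlations with replicates 2 and 3 were 0.949 and 0.944, under the 0.971 between these, so GC content did not remove the whole difference. As the whole source of the genes changed with HYOU1 shRNA the bias was argued against, since 96.2% of the 1526 calls stayed past the threshold in the same direction after the correction. No biological explanation was tested.

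KRT5, KRT13 and KRT14, keratins of squamous epithelium chosen after their values were seen, were at 29.1, 34.0 and 36.3 FPKM in control replicate 1 and between 3.21 and 8.40 FPKM in the other 5 libraries. GC bias was argued against, since after the correction their median difference from control replicates 2 and 3 was 2.94. Of 33 other squamous markers, 20 with a mean of at least 0.1 FPKM over all libraries and under 10 FPKM in control replicates 2 and 3 had a median GC-corrected difference of 1.41, but this selection favours markers that are higher in replicate 1. For the 25 markers with at least 0.1 FPKM in the HYOU1 shRNA libraries, a selection made after the first result and independent of the controls, the median was 0.64, above 100% of 10000 lists matched on expression in those libraries, with 10 higher by over 1 (KRT6A at 14.3 against 2.48 and 2.51 FPKM) and 4 lower, among them KRT16, S100A9 and CSTA. RNA of squamous epithelial cells in this library may account for part of the pattern and stays open, as does the sharing of reads between similar keratins, and no biological explanation was tested.

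Of 36 genes for secreted hepatocyte proteins, 31 were under 1 FPKM in the controls, which argues against a loss with HYOU1 knockdown. Too little depth was also looked at after the values were seen, and 3 fragments of ALB would have been worth at most 0.0520 FPKM. No housekeeping gene of 14 was listed at 0, and 23 of the 88 other protein-coding genes within 5 Mb of ALB were at 1 FPKM or more. These values argue against a loss in counting of genes in general or of that whole region. A loss in counting confined to the hepatocyte genes stays open. The 88 neighbours had a median of 0.013 FPKM, and a neighbour near 0 could be silent or lost, so they did not decide it. Whether the cells were the labelled line stays open as well, and genotypes are not used here.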
